A study of Homo sapiens with 4 samples.

How the data were processed

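Total RNA of 4 THP-1 samples, 2 untreated and 2 given LPS, was labelled with Cy3 and hybridised to one-colour Agilent arrays, per the labels' protocols. The labels name the samples of each group as biological replicates 1 and 2. Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.3.1 and the probe design refers to build hg19. The deposited intensity of each spot is a background-subtracted, spatially detrended signal with a floor near the noise of its array, per the file headers, and was not normalized between arrays. The deposited value table gave the same intensity for 11325 probes, with a largest relative difference of 1.2e-06 from the scanner values and column medians of 139 and 109 (control 1 and 2) and 130 and 145 (LPS 1 and 2). Its scale was therefore linear, with no centring. All of its probes were well above background on at least 1 array. Positions of probes in the genome were not used here.

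Control spots, and 600 spots of probes named as negative controls, were left out. Spots with an outlier flag (6.91% and 6.59% of spots on control arrays 1 and 2, 7.21% and 6.85% on LPS arrays 1 and 2) were also left out, and the spots of a probe were averaged. Values were log2 of the processed signal minus the 75th percentile of its array. Since under 50% of probes were well above background, the percentile was taken over probes well above background on all 4 arrays, where it was 1241 and 965 for control arrays 1 and 2 and 1158 and 1328 for LPS arrays 1 and 2. Scaled signals in the text are these values brought back to the linear scale at the mean reference level of the 4 arrays. Signal over background was lowest on control array 2: its lowest signal among probes well above background was 56.3, against 41.4, 37.1 and 34.2 on control array 1 and LPS arrays 1 and 2.

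A probe was tested when well above background on both arrays of at least 1 group, which 24384 probes met. Of these, 4695 with too few values after flagged spots were removed had no residual degrees of freedom and were left out, NEAT1 among them, leaving 19689. Of these, 1431 had 1 array left in a group, 153 of them among the changed probes, and their test takes its spread from the other group and the prior variance. Differences were estimated with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) as LPS minus control, with Benjamini-Hochberg adjustment and a threshold of adjusted p under 0.05. All p from limma are two-sided. "Rose", "fell" and "changed" refer to that threshold. A probe not well above background on either array of its dim group, or saturated on both arrays of its bright group, is given as "at least N-fold", from means of log2 values: the mean of the bright group against the mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. Such a bound covers the background limit of each array and saturation, not the spread between arrays, another floor or another scaling. The difference with a single floor, after normexp or with another scaling can lie under it. Tables were read with the R packages data.table (version 1.17.8) and jsonlite (version 2.0.0), and figures drawn with matplotlib 3.10.9 in Python 3.11.15.

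All 4 arrays came from 1 scan of 1 slide. Both groups had an array in each slide row, which goes with the replicate number, but each slide column held 1 group, so slide column and group cannot be told apart. A slide block was therefore not run.

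Names came from the array's own probe names. Of 65 RefSeq accessions among them, 63 were matched to a symbol through a reference table of assembly GRCh38.p14, used for names only; the others keep their accession. Probe classes (ultraconserved, nc-HOX, other known noncoding RNA, HOX exon, HOX intron, messenger RNA control) were taken from these names after the data were opened, as was the comparison inside and outside the deposited value table. Noncoding probes are the first 3 classes, and protein-coding probes are HOX exons and messenger RNA controls. Classes were compared with Fisher's exact test and, over probes measured on all arrays, limma camera (correlation 0.01, or estimated) and fry, each adjusted over 13 sets.

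The tests, gene lists and naming rule were set before the data were examined. The rule takes the 8 largest rises and 8 largest falls among noncoding probes and the 6 largest of each among protein-coding genes, past the threshold, at least 2-fold and well above background on both arrays of the brighter group, filled in by smallest p where fewer passed; up to 4 members of each gene list; and up to 2 unnamed probes per direction by identifier. TEAncRNAs, mascRNA, NEAT1, the saturated controls and other exons of named genes were named after their values were seen. A protein-coding probe that the rule names is not reported here. A planned test of noncoding probes within 100 kb of inflammatory genes was not run, since it needs probe positions.

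The fit was tested on simulated data with the spread of these arrays over 18258 probes. With 200 changed probes, 0% of those changed by 1 or by 2 on the log2 scale passed the adjusted threshold, and the sign was right for 100% of them. With 3249 changed probes, 14.8% of those changed by 1 and 83.4% of those changed by 2 passed, and 3.92% of 1660 calls were false. With 2 arrays per group, small changes were therefore seldom detected, and none was when few probes changed.

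Alternatives were normexp with offset 50, quantile normalization, the median or the 75th percentile of all probes as reference, no filter on dim probes, only probes well above background on all arrays, an intensity trend with robust variances, the replicate number as a block, the value table in place of the scanner files, saturated spots left out, and each array left out in turn. Normexp was run on the median spot and background signals, in place of the planned mean spot signal, which was not used here. Keeping outlier-flagged spots, a single floor on all arrays, and the share of rises inside and outside the value table with no filter were added after seeing the data.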

Results

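THP-1, a human monocytic leukaemia cell line, was profiled with and without lipopolysaccharide (LPS), the bacterial cell wall component that activates monocytes through Toll-like receptor 4. Total RNA from 2 control samples and from 2 samples given LPS at 100 ng/ml for 24 h was hybridised to 4 one-colour arrays designed for long noncoding RNA. Each array carried 62738 spots, of which 60819 were not controls and covered 60639 probes. The share of probes well above background was 40.3% and 33.6% on control arrays 1 and 2, and 42.2% and 42.1% on LPS arrays 1 and 2. On all 4 arrays 19428 probes were well above background, and on none of them 32086. Pearson's r across the tested probes was 0.971 between the control arrays and 0.970 between the LPS arrays, against 0.879 to 0.911 between a control and an LPS array. These correlations run across probes, which are not independent replicates. The SD of the difference between replicates was 0.65 on the log2 scale for control and 0.58 for LPS. The number of arrays limits the precision of every value.

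The comparison of LPS with control addresses which transcripts, long noncoding RNAs above all, differ after 24 h of LPS. Of 19689 tested probes, 3249 changed, 2359 upward and 890 downward, and 3227 of them had a fitted difference of at least 2-fold. Of the rises, 912 were well above background on neither control array, and of the falls 110 on neither LPS array. For these the fitted difference takes in signals near the floor, so it does not by itself show a 2-fold change. A further measure was detection: 1627 probes were well above background on both LPS arrays and on neither control array, and 146 showed the reverse. The unnamed probe ASHG19A3A009421 was at least 1073-fold higher with LPS (limma adjusted p = 0.0035) and was saturated on both LPS arrays. That bound holds at the reported scaling, with a log2 difference of 10.07. Over the alternatives the log2 difference of this probe ran from 9.87 to 10.2. The unnamed probe ASHG19A3A026205 was at least 92.2-fold higher (limma adjusted p = 0.0036), while ASHG19A3A017264 and ASHG19A3A044189 were at least 12.01-fold and at least 22.6-fold lower. These 3 bounds rest on each array's own background limit. With a single floor on all arrays the log2 differences were 6.12, -2.56 and -3.47, and after normexp background correction 5.84, -2.46 and -2.95, which passed but are smaller than the bounds. The array files give these probes only the array's own identifiers, so their genes are not given here. At an unadjusted p under 0.05, 6643 probes passed. The count fell when any single array was left out. Such a fit has a lone array in a group and fewer residual degrees of freedom. A call lost there, here or below, does not by itself show that the result rests on that array. With limma on the deposited value table alone 0 probes passed, with 2400 at an unadjusted p under 0.05 and 646 at an adjusted p under 0.1. No call on a named probe therefore passed on that table.

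The share of rises among changed probes was 72.6%. It was 62.5% after normexp background correction, 68.9% after quantile normalization, 63.7% with the median of all probes as reference and 59.7% with the 75th percentile of all probes. Among probes well above background on all arrays it was 56.6%, and with that filter and the 75th percentile of all probes together it was 39.9%, so the balance of rises and falls turned with these choices. The 75th percentile of all probes moved the median log2 fold change of all tested probes from 0.037 to -0.13.

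**Figure D1:**
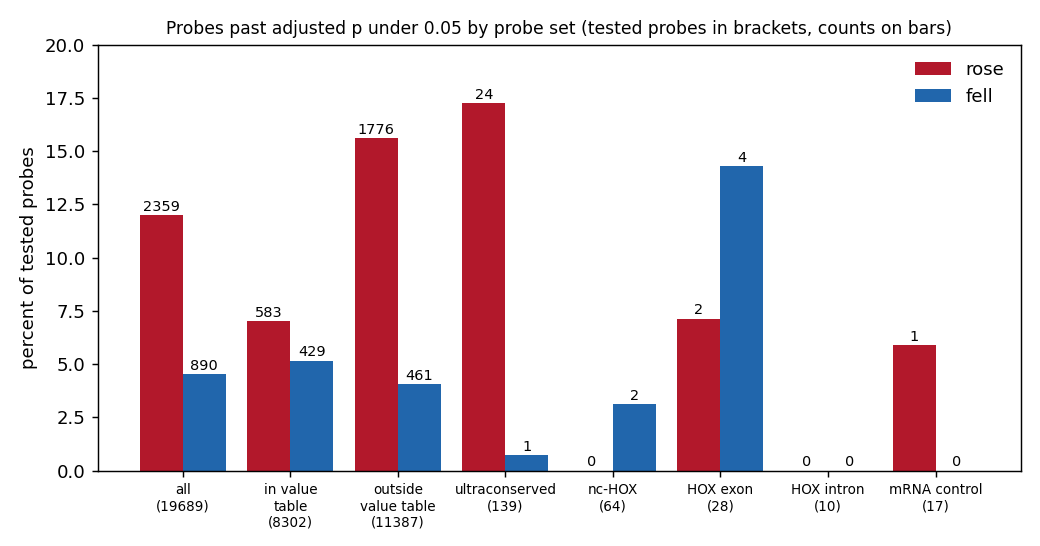
Percent of tested probes that rose (red) or fell (blue) with LPS at a limma adjusted p under 0.05, by probe set, with the number of tested probes in brackets and the number of changed probes on each bar. Rises were 24 of 139 ultraconserved probes and 0 of 64 nc-HOX probes, and 1776 outside against 583 inside the deposited value table.

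Among the probes classed as noncoding by their names on the array, 25 of 209 tested probes rose and 4 fell. Their share of rises, 11.96%, was near the 11.98% of all tested probes. Of the rises 24 of the 25, and of the tested probes 139 of the 209, belonged to ultraconserved regions, stretches of genome identical between human, mouse and rat. The array covers these with a probe for each strand. Whether an ultraconserved probe reads a noncoding or a coding transcript was not tested, since probe positions were not used. By the background limits of its own arrays, the probe uc.472- was at least 6.17-fold higher with LPS, with a scaled signal of 11.3 ± 3.17 (SD, n = 2) in control and 318 ± 27.2 (SD, n = 2) in LPS. Its limma adjusted p was 0.0045, and it also passed with a single floor on all arrays and after normexp, where its log2 differences of 2.22 and 1.95 were under that bound (limma adjusted p = 0.024 and 0.018). It was joined by uc.184+, which went from 122 ± 28.5 to 1570 ± 1343 (SD, n = 2 each; log2 fold change 3.38, SE 0.68, limma adjusted p = 0.032). The call of uc.184+ was lost after quantile normalization (limma adjusted p = 0.052), with a single floor (0.16) and without control replicate 1 or 2 (0.079 and 0.14). Its log2 fold change was 2.37 without LPS replicate 2, 4.39 without LPS replicate 1 and 2.72 after normexp. The other strand of the same element, uc.184-, was not well above background in control and was at least 1.35-fold higher (limma adjusted p = 0.026).

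Of the remaining large rises, uc.28+ had a log2 fold change of 3.03 (SE 0.69) and uc.24- of 2.70 (SE 0.57), each well above background on 1 control array. The probe uc.471+ rose by 2.81 on the log2 scale (SE 0.32), from 2926 ± 310.2 (SD, n = 2) to 20439 on the 1 LPS array whose spot carried no outlier flag; its SE rests on the control spread and the prior variance alone, and with flagged spots kept its log2 fold change was 2.46 (limma adjusted p = 0.026). Its call was lost with a single floor (limma adjusted p = 0.066) and on the value table (0.094). The probes uc.129+ and uc.151- were at least 2.32-fold and at least 1.71-fold higher. Limma adjusted p for these 5 probes lay between 0.0076 and 0.043. The calls of uc.28+ and uc.24- were lost after quantile normalization (limma adjusted p = 0.083 and 0.062) with the median of all probes (0.058 and 0.053), without control replicate 2 (0.13 and 0.059) and without LPS replicate 1 (0.080 and 0.13), and that of uc.28+ also with flagged spots kept (0.052) and with a single floor (0.20). The log2 fold changes of uc.28+ and uc.24- were 3.91 and 3.54 without control replicate 1, 2.13 and 1.82 without control replicate 2, 1.58 and 1.31 with a single floor and 1.34 and 0.94 after normexp; that of uc.28+ was 3.63 without LPS replicate 1 and 2.45 without LPS replicate 2. The calls of uc.184-, uc.129+ and uc.151- were lost after normexp (limma adjusted p = 0.33, 0.11 and 0.10), that of uc.184- without control replicate 1 or 2 (0.083 and 0.071) and that of uc.129+ without control replicate 2 (0.074). With a single floor on all arrays these 3 probes had log2 differences of 0.32, 0.81 and 0.37, under their bounds here, and did not pass; after normexp uc.129+ was also under its bound, at 0.77. The only ultraconserved probe that fell was uc.43+, with a log2 fold change of -1.67 (SE 0.39, limma adjusted p = 0.045), and it was well above background on 1 LPS array. Its call was lost under 9 of 15 alternatives, among them normexp (log2 fold change -0.80, limma adjusted p = 0.065), a single floor (-0.98, 0.074), no filter on dim probes (0.10), flagged spots kept (0.080) and any 1 array left out (0.067 to 0.14). The probes uc.263-, uc.403+ and uc.459- had log2 fold changes of -1.10, -0.96 and -1.08 and did not pass the test (limma adjusted p = 0.065, 0.071 and 0.091).

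Rises made up 17.3% of tested ultraconserved probes and 11.9% of all other tested probes, a difference that did not pass (Fisher's exact test, two-sided, adjusted p = 0.28 over 13 probe sets). Falls made up 0.719% against 4.55% (adjusted p = 0.15, same exact test). The median log2 fold change of the set was 0.32, with limma camera adjusted p = 0.10, and adjusted p = 0.59 with an estimated correlation. In 11 of the 24 risen probes neither control array was well above background. Over the 4 other scalings 11 to 23 ultraconserved probes rose and 1 to 3 fell. Without control replicate 1, 19 rose and 5 fell, without control replicate 2, 5 rose and 6 fell, without LPS replicate 1, 10 rose and 0 fell, and without LPS replicate 2 none passed.

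Among probes for noncoding transcripts of the 4 HOX clusters, which hold homeobox genes that pattern the body axis, no rise passed. Of 64 tested nc-HOX probes 0 rose and 2 fell. The 2 that fell were nc-HOXA13-98, from 411 ± 30.4 to 153 ± 19.5 (SD, n = 2 each; log2 fold change -1.43, SE 0.25, limma adjusted p = 0.022), and nc-HOXA13-99, from 6695 ± 571 to 3079 ± 429 (log2 fold change -1.12, SE 0.25, limma adjusted p = 0.041). Both calls were lost with no filter on dim probes (limma adjusted p = 0.12 and 0.25) and with any 1 array left out (0.056 to 0.12 and 0.086 to 0.19), and that of nc-HOXA13-99 also after quantile normalization (0.11), with the replicate number as a block (0.055), with flagged spots kept (0.055) and with a single floor (0.068). Their neighbour in the array's numbering, nc-HOXA13-100, had a log2 fold change of -0.99 and did not pass (limma adjusted p = 0.068). The share of rises was lower than among all other tested probes (0% against 12.02%, Fisher's exact test, two-sided, p = 0.00066, adjusted p = 0.0043). Limma camera did not place the set apart (adjusted p = 0.14, and adjusted p = 0.69 with an estimated correlation). Adjusted over the set alone, 0 of the 64 passed, with limma giving 4 at an unadjusted p under 0.05. Beside the 3 nc-HOXA13 probes above, these 4 include nc-HOXD9-16, which was higher in LPS. Its log2 fold change was 1.54 (SE 0.44), larger in size than either fall, and it did not pass (limma adjusted p = 0.074). Under each of the 4 other scalings 0 nc-HOX probes rose and 1 to 3 fell; without control replicate 2, 1 rose and 1 fell.

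Of 17 probes for other known noncoding RNAs, 6 were tested. CARIntergenic10 fell from 2414 ± 1108 to 528 ± 153 (SD, n = 2 each; log2 fold change -2.14, SE 0.42, limma adjusted p = 0.030), a call lost after normexp (limma adjusted p = 0.059), with a single floor (0.13) and without control replicate 1, LPS replicate 1 or LPS replicate 2 (0.069, 0.077 and 0.14). Its log2 fold change was -1.65 without control replicate 1 and -2.67 without control replicate 2. TEAncRNAs passed the test upward (limma adjusted p = 0.015), with scaled signals of 13.4 ± 0.265 in control and 50.4 ± 12.1 in LPS (SD, n = 2 each). It was not well above background on either control array, and its LPS mean did not exceed the limit of those arrays, so no fold is given. HOTAIRM1, a myeloid noncoding RNA of the HOXA cluster, had a log2 fold change of -0.80 (SE 0.28) and did not pass (limma adjusted p = 0.11). The probe for mascRNA, the small RNA cut from the MALAT1 transcript, had a log2 fold change of 0.96 (SE 0.24) and did not pass (limma adjusted p = 0.056). NEAT1, the RNA scaffold of nuclear paraspeckles, had outlier flags on its spots and was tested only with those spots kept, where its log2 fold change was 0.27 (SE 0.27, limma adjusted p = 0.54).

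**Figure D2:**
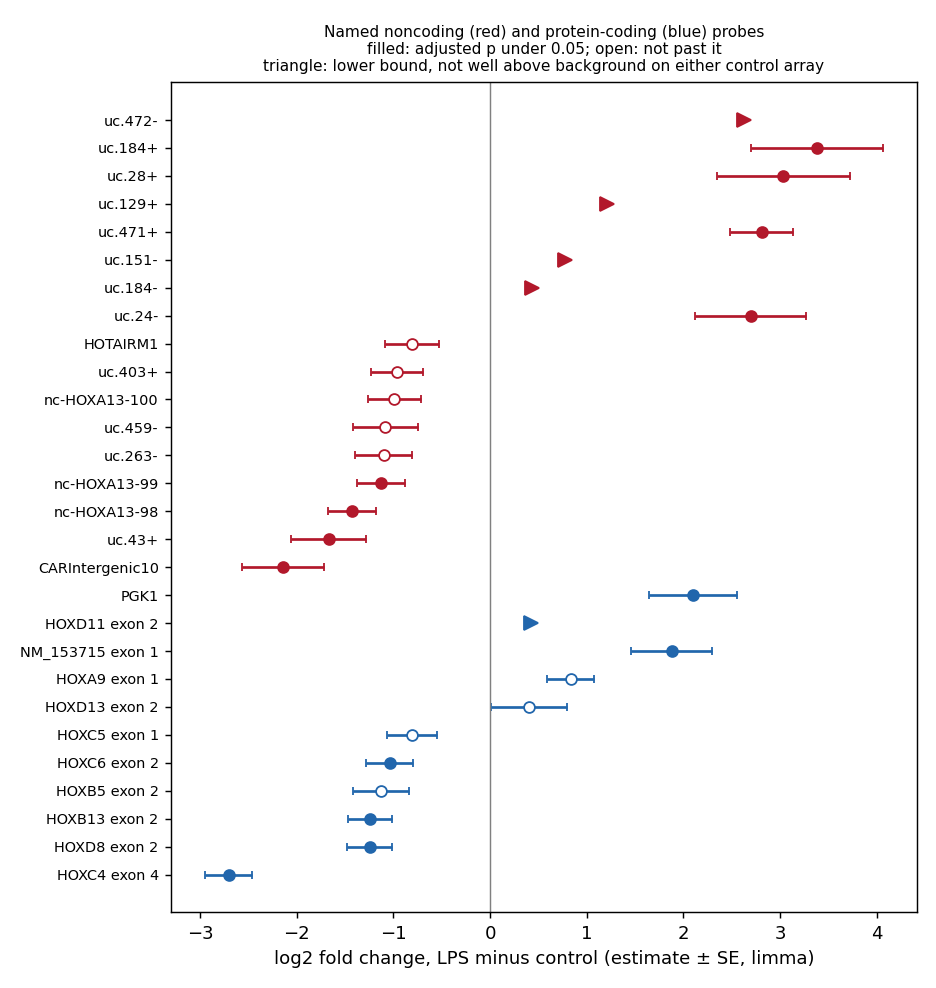
Log2 fold change (LPS minus control) of the named noncoding probes in red and protein-coding probes in blue, with its SE from limma; filled points passed a limma adjusted p under 0.05 and open points did not. Triangles mark passing probes that were not well above background on either control array, drawn at the bound from each array's own background limit, such as uc.472- at 6.17-fold; a single floor on all arrays gave uc.472- a log2 difference of 2.22, under that bound.

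The probes that the array names as protein-coding are exons of HOX genes and a panel of widely expressed control genes. Of the array's 60639 probes, 59273 carry no gene name, and any coding transcripts among them are not counted here. Of 45 named protein-coding probes tested, 3 rose and 4 fell, and all 4 falls were HOX exons. HOXC4 exon 4 fell from 583 ± 28.4 to 90.0 ± 11.8 (SD, n = 2 each; log2 fold change -2.70, SE 0.24, limma adjusted p = 0.0071), while HOXC4 exon 2 had a log2 fold change of -0.61 and did not pass (limma adjusted p = 0.16). HOXD8 exon 2, HOXB13 exon 2 and HOXC6 exon 2 fell by 1.25, 1.24 and 1.04 on the log2 scale (SE 0.23, 0.23 and 0.25, limma adjusted p = 0.027, 0.026 and 0.048). These 3 calls were lost with no filter on dim probes (limma adjusted p = 0.18, 0.18 and 0.30) and with any 1 array left out (0.066 to 0.18), and that of HOXC6 exon 2 also with the replicate number as a block (0.061), with flagged spots kept (0.080) and with a single floor (0.066). The call of HOXC4 exon 4 was lost, among the 15 alternatives that gave it a value, only without LPS replicate 2 (limma adjusted p = 0.059), and its log2 fold change was -2.11 after normexp. HOXD8 exon 1 had a log2 fold change of 0.30 and did not pass (limma adjusted p = 0.56). HOXB5 exon 2 and HOXC5 exon 1 had log2 fold changes of -1.13 and -0.81 and did not pass (limma adjusted p = 0.057 and 0.093).

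The control gene PGK1, a glycolytic enzyme, rose from 457 ± 248 to 1835 ± 441 (SD, n = 2 each; log2 fold change 2.10, SE 0.45, limma adjusted p = 0.038). Its control signal lay far under that of the control gene GAPDH (830875 ± 148838, SD, n = 2), and how well the probe reports its transcript was not tested. GAPDH was saturated on 3 arrays, both control arrays among them, so its control mean is a lower limit and its SD does not measure spread. PGK1 missed the threshold after quantile normalization and with the median of all probes as reference (limma adjusted p = 0.051 and 0.057). PGK1 also missed it with a single floor (0.15). Its log2 fold change was 2.69 without control replicate 1 and 1.47 without control replicate 2 (limma adjusted p = 0.029 and 0.11), and the call was also lost without LPS replicate 1 or 2 (0.098 and 0.16). HOXD11 exon 2 was not well above background in control and was at least 1.34-fold higher (limma adjusted p = 0.012), by the background limits of its own arrays. This call was lost after normexp (limma adjusted p = 0.15), without control replicate 2, LPS replicate 1 or LPS replicate 2 (0.057, 0.067 and 0.070), and with a single floor, where its log2 difference of 0.058 was under the bound (0.60). HOXD11 exon 1 had a log2 fold change of 0.36 and did not pass. An exon 1 probe of NM_153715, an accession with no match in the reference table, rose with a log2 fold change of 1.88 (SE 0.42, limma adjusted p = 0.042). Its call was lost under 8 of 14 alternatives: after quantile normalization and with the median of all probes (limma adjusted p = 0.065 and 0.061), with no filter on dim probes (0.071), flagged spots kept (0.052) or a single floor (0.13), and without control replicate 2, LPS replicate 1 or LPS replicate 2 (0.16, 0.075 and 0.17). The log2 fold change of NM_153715 exon 1 was 1.19 after normexp. HOXA9 exon 1 and HOXD13 exon 2 had log2 fold changes of 0.83 and 0.40 and did not pass (limma adjusted p = 0.076 and 0.52). The value for HOXD13 exon 2 was -0.15 after normexp. ACTB, RPLP1, ACTG1 and RPS18 were saturated on all 4 arrays, so no fold change is given for them. Of 28 tested HOX exons 2 rose and 4 fell, and of 10 tested HOX introns 0 changed, with limma giving 1 at an unadjusted p under 0.05. Across the 4 other scalings 1 to 3 protein-coding probes rose. In place of 7 changed protein-coding probes, 1 passed without control replicate 2, 1 without LPS replicate 1 and 0 without LPS replicate 2.

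The deposited value table, a selection of 11325 of the array's probes, held 292 of the 301 named noncoding probes well above background on at least 1 array, and 0 of the 64 protein-coding ones. The rule behind the selection is not given in the sources used here. Inside it 583 of 8302 tested probes rose and 429 fell, and outside it 1776 of 11387 rose and 461 fell. Rises were less frequent inside than outside (7.02% against 15.6%, odds ratio 0.41, Fisher's exact test, two-sided, adjusted p = 1.22e-77 over 13 probe sets). With no filter on dim probes the direction turned, 3.16% of 10491 inside against 2.38% of 45453 outside, where most probes were well above background on no array; over probes well above background on at least 1 array, as all of the table's are, it was 3.16% against 8.10%. Fisher's exact test takes probes as independent, which they are not, so its p can overstate the evidence. Falls were more frequent inside (5.17% against 4.05%, adjusted p = 0.0030, same exact test). Adjusted over the table alone, 721 probes changed and 443 of them rose. The median log2 fold change inside the table was -0.064 and the mean was 0.027, opposite in sign; limma camera placed the set below the other probes (adjusted p = 0.016, and adjusted p = 0.59 with an estimated correlation), and limma fry, which asks whether the set moved one way, gave p = 0.63.

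Among changed probes 57.6% rose inside the table and 79.4% outside it. Inside the table this share was 43.6% after normexp, 50.1% after quantile normalization, 46.3% with the median of all probes and 41.9% with the 75th percentile of all probes, while outside it ranged from 69.0% to 77.7% over the same scalings. The inside share was 37.0% among probes well above background on all arrays and 46.6% with a single floor on all arrays.

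**Figure D3:**
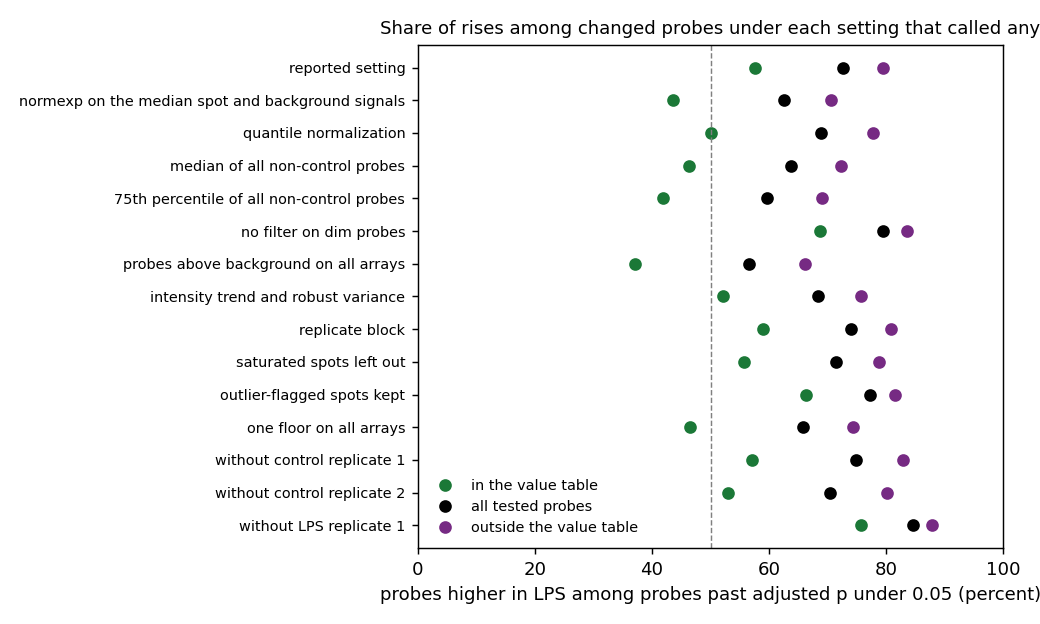
Percent of changed probes that were higher with LPS, for probes inside the deposited value table (green), outside it (purple) and all tested probes (black), under the reported setting and each alternative that called any probe; the dashed line marks 50%. The green point lies left of the purple point in every line, at 57.6% against 79.4% in the reported setting, and crosses 50% in several.

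Of 11 gene lists with 374 distinct genes fixed before the data were examined (cytokines and chemokines, NF-kappaB pathway, interferon response, monocyte and macrophage markers, cell cycle, stress, lipid handling, lncRNAs linked to innate immunity, small RNA host genes, abundant nuclear RNAs, and markers of other cell types), only NEAT1 and HOTAIRM1 matched a named probe, and 1 of them was tested. No list reached 5 tested members, so no list was tested as a group.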

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

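Keeping outlier-flagged spots, the single floor, the value table and ultraconserved sets and their shifts were chosen after the data were seen; the other settings were planned. The cause of each change below was not tested, except where fewer arrays or probes entered. With 2 arrays per group, and control array 2 the dimmest, signal over background limits dim probes most. A fit with an array left out also has fewer residual degrees of freedom, so calls lost there can reflect lost power alone.

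The total of 3249 changed probes was 1778 with no filter on dim probes, 2134 among probes above background on all arrays, 1226 with a single floor, 5232 at an adjusted p under 0.1, 6643 at an unadjusted p under 0.05, and 0 on the series value table. In limma that table gave 2400 at an unadjusted p under 0.05. The 29 changed noncoding probes became 15 after normexp, 19 after quantile normalization, 12 among probes above background on all arrays, 6 with a single floor and 0 on the value table. The 7 changed protein-coding probes became 3 with no filter and 4 with a single floor. The 1012 changed value-table probes became 482 with no filter, 378 with a single floor and 0 on the table's own values. The 24 risen ultraconserved probes became 11 after normexp, 15 after quantile normalization, 8 among probes above background on all arrays, 5 with a single floor and 0 on the table's own values. Every other total for these sets, with all arrays in, was within 1.5 times of the reported one. Counts by direction moved further: among them, the 2359 rises became 1407 after normexp, the 583 rises inside the value table became 294, and the 890 falls became 1341 with the 75th percentile of all probes and 364 with no filter.

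Leaving out 1 array at a time, with the lone array assumed to vary like the other group, gave 0 to 2303 changed probes, 0 to 27 noncoding, 0 to 4 protein-coding and 0 to 714 value-table probes, and 0 to 19 risen ultraconserved probes. The 0 in each came without LPS replicate 2, where limma gave 4852 probes at an unadjusted p under 0.05. The median log2 fold change ranged from -0.18 to 0.020 for the value table and from 0.088 to 0.53 for ultraconserved probes. Without LPS replicate 2 the value-table median was 0.020, and its shift no longer passed in camera. Without LPS replicate 1 the ultraconserved median was 0.53, and its shift passed. Over all settings the ultraconserved shift had a camera adjusted p of 0.00080 to 0.59.

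With no filter, where the median of all probes was -0.37, the value table lay at -0.068, above the other probes, and ultraconserved probes at -0.42, below them, neither past the threshold. With flagged spots kept, the value-table median was 0.0089 and its shift no longer passed (adjusted p = 0.14), and the ultraconserved median was 0.41 and passed (adjusted p = 0.048). With an estimated correlation the value-table median of -0.064 did not pass. On the value table's own values the ultraconserved median was 0.46 and passed (adjusted p = 0.00080).

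The replicate block gave 3278 changed probes, 2841 of them shared with the reported 3249. The difference between replicates 1 and 2 in control and that in LPS had a correlation of 0.060 across probes. The numbers were therefore not taken to pair the samples. Of 493 values of named probes under the alternatives, 370 kept direction and side of the threshold, 113 lost the threshold, 9 passed it and 1 reversed: HOXD13 exon 2 at -0.15 after normexp. No gene list test, neighbourhood test, mean over a gene's probes or slide block was run.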

Other observations

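Of 17 probes for known noncoding RNAs, 9 were well above background on no array, among them lincRNA-p21, Sox2ot (SOX2-OT) and Air (AIRN). The probe for lincRNA-RoR had a processed signal of 194 on LPS array 2 and lay at or near the floor on the other arrays (8.25, 11.2 and 7.40), so it entered no test. HOXA9 exon 2, a part of a homeobox gene known for high expression in myeloid leukaemia, had a scaled signal of 48598 on the 1 control array without an outlier flag and a mean of 61566 on 2 LPS arrays and did not pass the test (log2 fold change 0.32, SE 0.37, limma adjusted p = 0.61). The probe Alpha250 had a log2 fold change of -0.66 (SE 0.26) and did not pass (limma adjusted p = 0.15). These items were chosen after their values were seen.

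The array's own identifiers fall into 3 series by their letter. In series A, 3162 of 18782 tested probes changed, in series L 47 of 545, and in series H 4 of 95. What the letters stand for is not given in the sources used here. Dark corner spots, which carry no target sequence, were well above background for 17.1% of 35 spots on LPS array 1 and 0% on each of the other arrays.

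Of the tests below, those of scaling alone and of background alone for the first pattern, that of noncoding against messenger RNAs for the second, and that of a single RNA for the third, were chosen after the values were seen. The test of the filter on dim probes for the second pattern was also added after the data were seen. The first pattern is the excess of rises, 72.6% of changed probes. The lowest share over the 4 other scalings was 59.7%, and the share among probes above background on all arrays was 56.6%, but neither excludes scaling or probes near background as a cause, since the reference level sets the balance. Both together took the share to 39.9%, so the excess may come from the choice of reference level and from dim probes that crossed the background limit in LPS. A shift of many transcripts upward with LPS stays open as a biological hypothesis and was not tested.

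The second pattern is that rises were less frequent inside the deposited value table than outside it, except with no filter over all probes, most of them dark outside the table, where the odds ratio was 1.33. A difference in signal level is argued against by the odds ratio of rising within 20 bins of mean signal, 0.37 (95% interval 0.33 to 0.41). It was 0.41 without bins, and the share was lower inside the table in 20 of the 20 bins. This interval and those below take probes as independent, which they are not, so they can be too narrow. Scaling is argued against by the odds ratio nearest to 1 over the 4 other scalings, 0.40 (0.36 to 0.45). With no filter in the fit, over probes above background on at least 1 array, the odds ratio was 0.37 (0.32 to 0.42). This argues against the filter's demand for both arrays of a group as the source. It still leaves out probes dark on all arrays, so it cannot decide on detection itself. The table held nearly all detected named noncoding probes and 0 of the 64 named protein-coding ones, so a candidate explanation is that it selects noncoding RNAs and that these rose less often than messenger RNAs in LPS. Among named probes, whose class comes from their names alone, the shares ran the other way. Rises made up 11.96% of 209 noncoding and 6.67% of 45 protein-coding probes (odds ratio 1.90, 95% interval 0.54 to 10.3, Fisher's exact test, two-sided, p = 0.43). This leaves the explanation open, as does the unknown rule of selection.

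The third pattern is that both strands of an ultraconserved element moved together. Over 18 elements with both strands tested, Pearson's r between the log2 fold changes was 0.65 (permutation p = 0.0040, adjusted p = 0.018 over 5 relations). Spearman's rho was 0.60 (permutation p = 0.0092, adjusted p = 0.018), and r was 0.63 without the 2 farthest elements (permutation p = 0.011). Of 8 such elements with a risen strand 6 had both risen. Risen strands whose other strand was not tested, such as uc.472-, are not counted here. In uc.174, uc.184, uc.203 and uc.313, all among those 6, a strand was well above background on neither control array. The same held in uc.131, uc.173, uc.452, uc.455 and uc.50. Such a strand entered the test only through its LPS signal, which favours a rise. After the trend of fold change on signal was removed over all tested probes, r was 0.39 (95% bootstrap interval -0.022 to 0.74, permutation p = 0.11), which neither excludes nor shows that dim probes shifting together may be the source. Labelling of both strands of a single RNA could not be tested, since only 3 elements were above background on all arrays on both strands. Their plus and minus strands had log2 fold changes of 0.55 and 2.16 (uc.77, SE 0.24 each), -0.29 and -0.58 (uc.188) and 1.11 and 0.47 (uc.289). In none of these had both strands risen. Pearson's r over them was 0.48 (permutation p = 0.83), which so few elements cannot settle. LPS-driven transcription of both strands stays open as a hypothesis, and elements are across one set of 4 arrays and are not independent replicates.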
